A study of Rattus norvegicus with 16 samples.

How the data were processed

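Total RNA from kidneys of male Wistar rat pups was sequenced after left uninephrectomy or sham surgery on day 1 or day 14 of life, with the tissue taken 3 days after surgery, per the labels. Each group had 4 libraries. Per the labels' protocols, genomic DNA was removed with DNase, libraries were made with the Ovation Universal kit, and unwanted sequences were depleted with oligonucleotides designed for rat. BWA 0.7.14, STAR 2.4.0, Subread 1.5.1, featureCounts and DESeq2 are named in the submitters' processing notes, without their roles or order. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here, so reads shared between near-identical or overlapping genes cannot be set apart. The deposited values were regularised-log (rlog) expression levels on a log2 scale, as the deposited table's name and the values show, with 1 row per Ensembl rat gene. The rlog transform scales libraries for depth and pulls the differences of weakly expressed genes towards the gene's mean, so it understates their changes. Whether it was run blind to the groups is not given in the sources used here.

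Groups and library numbers came from the sample titles. The table's columns name the groups by surgery and day, and those headed CO were taken as the sham libraries of the same day and number. The labels list the libraries as separate samples and speak of pups divided into groups, but do not say that each library came from a separate pup, so p-values measure the spread between these samples. No pair of libraries held identical values. There were 26689 rows, of which 22715 varied between libraries, and the 14845 with a mean value of at least 3 over the 16 libraries were tested.

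Counts were not used here, so the test was limma 3.58.1 in R 4.3.3 on the rlog values, with 1 mean per group over all 16 libraries (12 residual degrees of freedom), empirical Bayes moderation with a mean-variance trend (6.88 prior degrees of freedom), two-sided p-values and Benjamini-Hochberg adjustment over the tested genes, called at adjusted p under 0.05. Fitted contrasts were UNX against sham at each age, their average, their difference, and sham day 14 against sham day 1. Intervals are 95% limma intervals. Correlations of effects were compared with 100 relabellings within age. The slope along the age difference averaged over all splits of the shared sham group into 2 and 2 and was compared with all 70 relabellings. Smaller comparisons used two-sided exact permutation tests in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Plots were drawn with matplotlib 3.10.9.

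The groups, tests, threshold, filter, gene lists and most alternatives were fixed before the data were examined. The rule for naming genes took, per contrast, the 10 largest rises and the 10 largest falls among genes with a symbol that passed the test with values that did not overlap, members of fixed gene lists that passed, and a fixed set of kidney genes. The reference table used for names matched 0 of the 26689 identifiers, so the rule named no gene and 0 of the 45 fixed gene lists could be tested. The identifiers printed, 2 that rose and 2 that fell after UNX, were chosen after their values were seen, and so was ENSRNOG00000051257. What kinds of genes changed is therefore not analysed here.

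Depth was not given as read totals. A gene seen in 1 library is given, in every other library, a value that falls as that library's depth rises, and 151 such genes ordered the 16 libraries by depth with 99.6% agreement over pairs of libraries. A gene was used when its highest value lay over 20 times further from the next than the other 15 spanned. On simulated data 12 of 12 genes with reads in 1 library only returned the true order. Whether each of the 151 genes was seen in 1 library only was not checked. The order says nothing about absolute depth, so no interval for counting error was computed.

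The test was tried on simulated data for the 14845 genes, with 200 changed. For UNX against sham after surgery on day 1 it recovered 33% of changes of 0.25, 97% of 0.5 and 100% of 1 on the log2 scale, with 6, 8 and 9 false calls. For the day 14 comparison it recovered 39.5%, 97.5% and 99.5%, with 4, 8 and 16 false calls. With fewer than 200 genes changed the Benjamini-Hochberg adjustment is stricter, so lower recovery would be likely. With a simulated slope of 0.1 along the age difference, the slope was returned as 0.093 for day 1 and 0.097 for day 14.

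Alternatives changed the filter on low values, the scaling, the variance model, the libraries in the fit, a block for the library number, the threshold and each library in turn. Fits without libraries doubted after the data were seen were added. Near-silent genes were the 5051 varying genes with a mean value under 0. They were outside the tests of surgery and age.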

Results

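Gene expression was measured by RNA sequencing of total kidney RNA from male Wistar rat pups that lost the left kidney (uninephrectomy, UNX) or had a sham operation in early postnatal life. Surgery took place on day 1 or day 14 of life and the kidneys were taken 3 days later. Each of the 4 groups, UNX day 1, sham day 1, UNX day 14 and sham day 14, held 4 libraries, 16 in all. The values were regularised-log (rlog) expression levels on a log2 scale for 26689 rat genes, of which 3974 stood at 0 in every library and 14845 had a mean value of at least 3 and were tested. Genes are given by their Ensembl identifiers, since the files do not pair the identifiers with gene names. Differences are rlog differences, which the transform shrinks, most of all for weakly expressed genes. Read totals are not given in the sources used here, so the absolute depth of each library is unknown. The order of the libraries by depth could be read from the values that the transform gave to undetected genes, and the deepest library exceeded the shallowest by at least 2.03-fold.

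Age separated the kidneys far more than surgery did. A batch that followed the surgery day, if there was one, could not be told apart from age. The first principal component held 66.3% of the variance and set all 8 libraries from day 1 surgery, at −20.7 to −16.4, apart from all 8 libraries from day 14 surgery, at 14.8 to 24.5. Pearson correlations across genes ran from 0.996 to 0.999 between libraries of a group and from 0.985 to 0.992 between libraries of different ages. The second component held 6.04% of the variance and set sham day 1 library 3, at −14.5, and sham day 14 library 4, at −12.9, apart from the other 14 libraries, at −2.58 to 5.95. On the first component the UNX libraries lay within the range of the sham libraries at each age. On the second, the UNX day 1 libraries, at 2.29 to 3.19, all lay above the sham day 1 libraries, at −14.5 to 2.09, while the UNX day 14 libraries, at −0.76 to 5.95, overlapped the sham day 14 libraries, at −12.9 to 3.26.

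**Figure D1:**
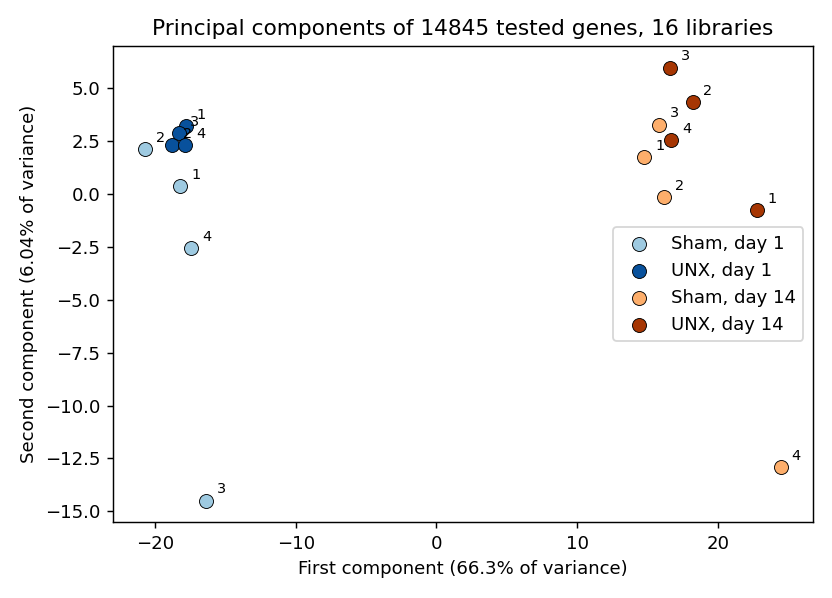
Each point is a library, placed by its scores on the first component (horizontal axis, 66.3% of the variance) and the second component (vertical axis, 6.04%), with no unit; colours mark the group and digits the library number. The libraries split by age along the first component, and sham day 1 library 3 and sham day 14 library 4 sit lowest on the second, at −14.5 and −12.9.

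The sham kidneys were compared first, to describe the change with age against which early nephron loss was set. Between the sham day 1 and sham day 14 groups, 6696 of 14845 genes (45.1%) differed, 3358 higher and 3338 lower at the older age (limma, Benjamini-Hochberg adjusted p under 0.05). Most of these differences were small, with a median size of 0.28 on the log2 scale. Differences of at least 1 were found in 100 genes that rose and 87 that fell, and differences of at least 2 in 7 that rose and 8 that fell. The largest difference upwards was 2.67 and the largest downwards −3.39. In 5455 genes (36.7%) the 4 values of one age did not overlap the 4 of the other, against 2.86% by chance. When a difference of at least 0.5 was also required, 1234 genes remained past both thresholds.

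The kidney that was left after UNX on day 1 differed from the sham kidney in 1 of 14845 genes. This gene, ENSRNOG00000017524, fell from 5.25 ± 0.042 in sham kidneys to 4.95 ± 0.025 in UNX kidneys (rlog value, SD, n = 4 each), and the 4 UNX values all lay under the 4 sham values. The log2 difference was −0.30 (SE 0.047, 95% interval −0.40 to −0.21), a level 19.0% lower (limma adjusted p = 0.0483). The same gene stood at 4.27 ± 0.018 in sham and 4.31 ± 0.046 in UNX kidneys after surgery on day 14 (n = 4 each), a difference of 0.03 that did not pass the test (limma adjusted p = 0.803). Between the sham groups it fell by 0.97 on the log2 scale with age, a comparison that uses the same sham day 1 libraries.

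The fall of ENSRNOG00000017524 was close to the threshold and was not past it in 15 of 20 alternative settings, among them each fit without 1 of the 8 day 1 libraries, with adjusted p from 0.0071 to 0.226 over all 20. The count of 1 gene became 0 when any of UNX day 1 libraries 1 to 4 or sham day 1 libraries 1, 2 or 4 was left out, and 2 without sham day 1 library 3. Chance was not excluded for this count, since 3 of 35 splits of the 8 day 1 libraries, the real one included, gave at least 1 gene. At an unadjusted p under 0.05 there were 1061 genes (7.15%, 501 higher and 560 lower), where 742.25 would be expected with no difference. The median size of the difference over all tested genes was 0.048, and the median half-width of its 95% interval was 0.136. In 669 genes (4.51%) the UNX and sham values did not overlap, against 2.86% by chance. The sham day 1 libraries were placed lower in the order of depth, with a mean rank of 12.75 against 5.5 for UNX day 1, where rank 1 is the deepest (two-sided exact permutation test, p = 0.057, n = 4 each).

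UNX on day 14 was followed by a difference from the sham kidney in 8 genes, 5 higher and 3 lower (limma adjusted p under 0.05). The UNX and sham values did not overlap in 6.97% of all tested genes, and in each of the 8, which were selected on these same values. The rises ran from 0.26 to 0.55 on the log2 scale and the falls from −0.28 to −0.42, in genes with mean rlog values of 8.95 to 12.9.

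ENSRNOG00000000590 rose most among the 8, from 10.3 ± 0.12 in sham kidneys to 10.8 ± 0.18 in UNX kidneys (n = 4 each). Its log2 difference was 0.55 (SE 0.082, 95% interval 0.38 to 0.72), a level 46.2% higher (limma adjusted p = 0.0176). In UNX day 14 library 4 this gene stood at 10.6, while the other 3 UNX libraries each stood at 10.9. Its UNX and sham means after surgery on day 1 were both 10.1, with a difference of −0.02 (limma adjusted p = 0.975).

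ENSRNOG00000018215, the most abundant of the 8, rose from 13.1 ± 0.10 to 13.5 ± 0.11 (n = 4 each). The log2 difference was 0.43 (SE 0.062, 95% interval 0.30 to 0.56), a level 35.2% higher (limma adjusted p = 0.0174). The same gene differed after surgery on day 1 by 0.14 (95% interval 0.01 to 0.27), which did not pass the test (limma adjusted p = 0.687). Its level in sham kidneys was 0.53 higher on the log2 scale at the older age, a comparison that uses the same sham day 14 libraries.

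ENSRNOG00000006060 fell most among the 8, from 9.34 ± 0.13 to 8.92 ± 0.12 (n = 4 each). The log2 difference was −0.42 (SE 0.067, 95% interval −0.56 to −0.28), a level 25.2% lower (limma adjusted p = 0.0277). The same gene differed after surgery on day 1 by −0.14 (95% interval −0.28 to −0.00052), which did not pass the test (limma adjusted p = 0.694). Its level in sham kidneys was 0.50 higher on the log2 scale at the older age, a comparison that uses the same sham day 14 libraries.

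**Figure D2:**
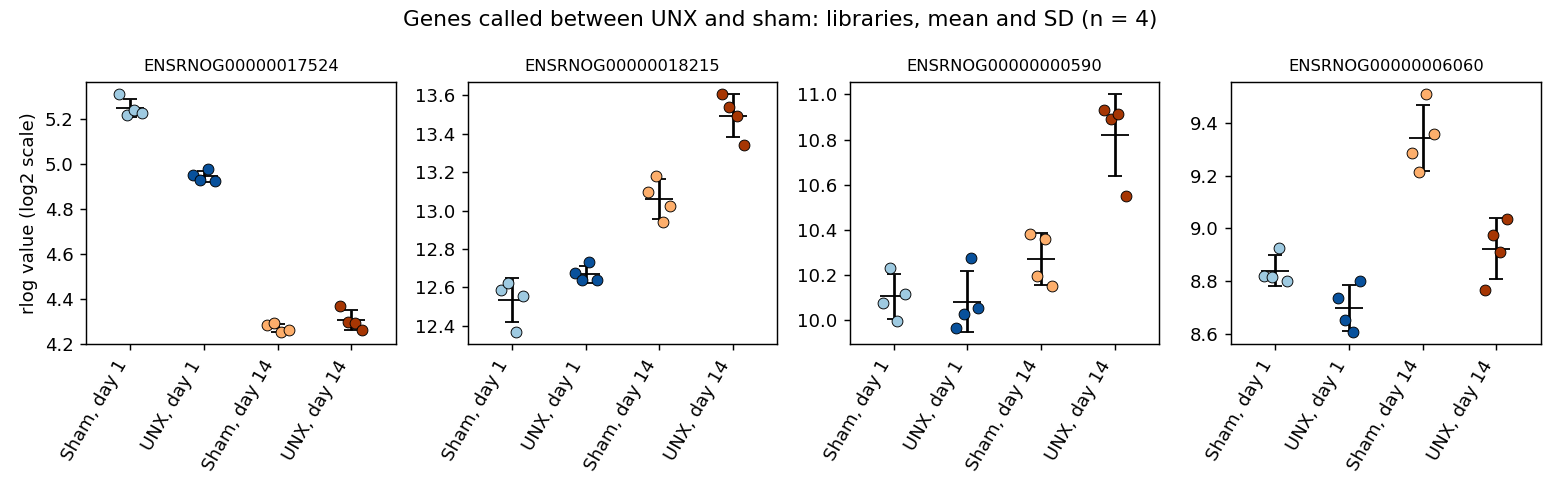
Points are rlog values (vertical axis, log2 scale) of single libraries in the 4 groups (horizontal axis), with the mean as a dash and the SD as bars, n = 4; each panel has its own scale and does not start at 0. ENSRNOG00000017524 passed the test of UNX against sham after surgery on day 1, and the other 3 genes after surgery on day 14.

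Chance was not excluded for the day 14 count, since 2 of 35 splits of the 8 day 14 libraries, the real one included, gave at least 8 genes. The count also rested on single libraries. It was 0 without UNX library 1, UNX library 2 or sham library 3, 2 without UNX library 3 or sham library 4, 22 without sham library 2 and 90 without UNX library 4, and it was 1 when UNX libraries 1 and 3, which held extra signal in near-silent genes, were left out together, a gene that was not among the 8. ENSRNOG00000000590, ENSRNOG00000018215 and ENSRNOG00000006060 were no longer past the threshold in 9, 7 and 12 of 22 alternative settings each, with limma adjusted p of at most 0.669, 0.349 and 0.738. Each kept its direction in all 22, but its UNX and sham values did not overlap, so leaving out libraries could not have reversed it. In the same order, the log2 differences ran from 0.45 to 0.64, 0.38 to 0.49 and −0.46 to −0.34 over these settings. For each gene the highest adjusted p came from the fit without UNX libraries 1 and 3. At an unadjusted p under 0.05 there were 2132 genes (14.4%, 1166 higher and 966 lower), where 742.25 would be expected. That number was 1003 without UNX libraries 1 and 3, 1086 without 2 and 3 and 1188 without 1 and 2. It was 1847 to 2205 without library 4 and any other. Each of these fits kept only 2 UNX libraries. In 1034 genes (6.97%) the UNX and sham values did not overlap, against 2.86% by chance. The median size of the difference over all tested genes was 0.059, and 12 genes differed by at least 0.5, of which 1 passed the test.

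**Figure D3:**
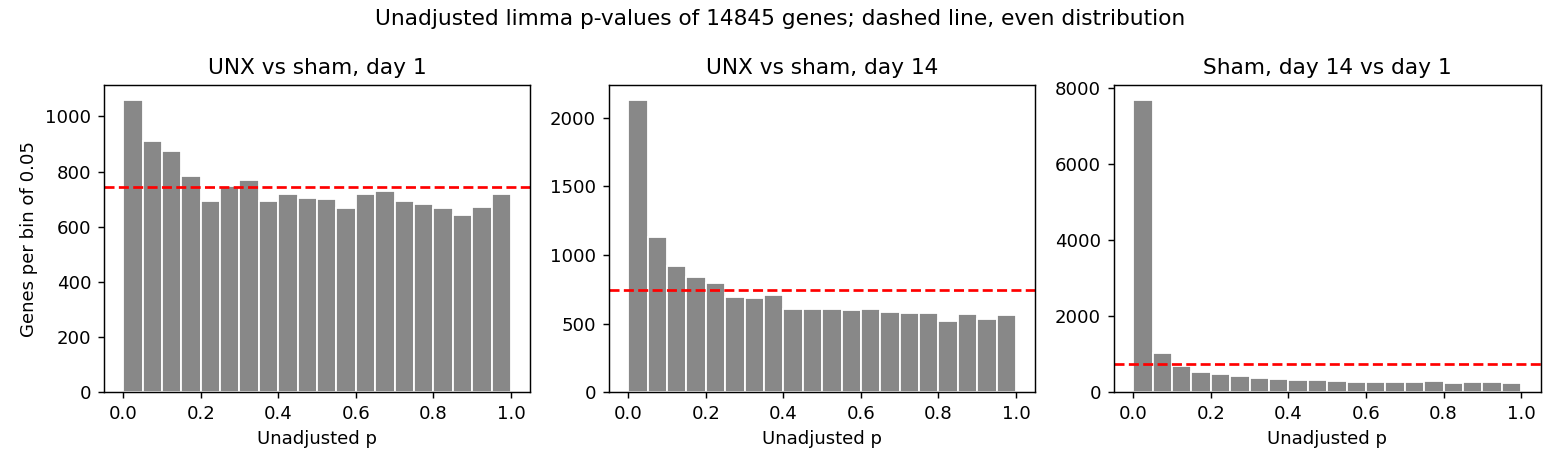
Number of genes (vertical axis) in each interval of 0.05 of the unadjusted limma p-value (horizontal axis) in 3 comparisons, with a dashed line at the 742.25 genes per interval of an even distribution; the vertical scales differ. The first interval holds 1061 genes for UNX against sham after surgery on day 1, 2132 after surgery on day 14 and 7697 for sham day 14 against sham day 1.

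A comparison of UNX with sham averaged over both ages tested the mean of the 2 differences, which a difference at 1 age alone can move. It gave 1 gene, ENSRNOG00000018215, which was higher after UNX by 0.29 on the log2 scale (SE 0.044, 95% interval 0.19 to 0.38; limma adjusted p = 0.0484). The difference of ENSRNOG00000018215 was 0.43 after surgery on day 14 and 0.14 after surgery on day 1, so a response common to both ages was not shown. At an unadjusted p under 0.05 there were 1579 genes in the averaged comparison. The count was 0 without UNX day 1 library 1, 2 or 3, sham day 1 library 3 or 4, UNX day 14 library 2, or sham day 14 library 1, 3 or 4. It was 2 without sham day 1 library 1, 3 without sham day 14 library 2 and 10 without UNX day 14 library 4. Without UNX day 1 library 4 or UNX day 14 library 1 or 3 the count stayed at 1, but ENSRNOG00000018215 was not the gene that passed.

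Whether UNX acted differently at the 2 ages was tested as the difference between the effects of UNX. In limma, 0 genes passed, with a smallest adjusted p of 0.058 and 1586 genes at an unadjusted p under 0.05. ENSRNOG00000000590 differed between the ages by 0.57 (95% interval 0.33 to 0.82; limma adjusted p = 0.134) and ENSRNOG00000017524 by 0.34 (95% interval 0.20 to 0.47; limma adjusted p = 0.134), so an age-specific effect was not established for either. The count was 5 without sham day 1 library 3, 2 without UNX day 14 library 3 and 1 without UNX day 14 library 4. The 1 gene that passed after surgery on day 1 was not among the 8 that passed after surgery on day 14. With so few genes that was likely in any case, and it does not bear on age-specific effects.

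Across the 14845 genes, which are not independent replicates, the effects of UNX at the 2 ages were close to uncorrelated (Pearson r = 0.052, Spearman rho = 0.00031, covariance 0.00050). Of 100 random relabellings of UNX and sham within each age, 82 gave an r as far from 0, over a range of −0.247 to 0.255. Its sign was not stable, and r was −0.043 without sham day 14 library 4, −0.013 without sham day 1 library 3, −0.0075 without UNX day 14 library 3 and −0.0011 without UNX day 1 library 3. These effects share no library.

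The last comparison asked whether the kidney after UNX lay towards the younger or the older expression pattern. Over the 6696 genes that changed with age, the UNX difference was regressed on the age difference, with the sham libraries split so that none served both differences. The genes themselves were chosen with all sham libraries and stayed the same in each relabelling, so the split did not fully free the slope of shared libraries. The slope after surgery on day 1 was 0.018, a shift of 1.79% of the age difference towards the older pattern (two-sided exact permutation test, p = 0.643, 45 of 70 relabellings as far from 0). It was −0.017 after surgery on day 14, a shift of −1.72%, towards the younger pattern (two-sided exact permutation test, p = 0.757, 53 of 70). Neither differed from 0 by more than relabelled libraries did, and neither sign was stable. The day 14 slope was 0.033, towards the older pattern, without sham day 14 library 4, 0.00011 without UNX day 14 library 3 and −0.048 without UNX day 14 library 1, and the day 1 slope was −0.0018 without sham day 1 library 2. The smallest p that 70 relabellings allow is 0.014.

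The share of the summed back-transformed values taken by the 20 most abundant genes was compared in 3 tests. With 4 libraries against 4 the smallest exact p is 0.029, so a single comparison could not pass after adjustment over 3 tests. The share was 22.1% ± 0.51 in UNX and 20.8% ± 0.61 in sham day 1 kidneys (two-sided exact permutation test, p = 0.057, n = 4 each, 0.086 after Benjamini-Hochberg adjustment over 3 tests). In day 14 kidneys it was 24.3% ± 1.11 after UNX and 23.1% ± 0.85 after sham surgery (exact permutation p = 0.20, adjusted 0.20). All 4 sham day 14 values lay above the 4 sham day 1 values (exact permutation p = 0.029, the smallest possible, adjusted 0.086).

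A single gene, ENSRNOG00000051257, chosen after its values were seen, was either high or low with nothing between. It stood at 12.2 in sham day 1 library 1, 12.3 in sham day 1 library 3 and 12.4 in sham day 14 library 4, and between 4.77 and 5.23 in the other 13 libraries. The gap of 6.94 on the log2 scale was 123-fold in rlog values. Among the 13 low values, the lowest was in the deepest library, sham day 14 library 3. The highest of them was in the shallowest, sham day 1 library 2. Values given to undetected genes also fall as depth rises, so the fold may be only a lower limit. Since 2 of the 4 sham day 1 libraries were high, its UNX difference after surgery on day 1 was −3.79, with a 95% interval from −7.08 to −0.50, and did not pass (limma adjusted p = 0.644).

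**Figure D4:**
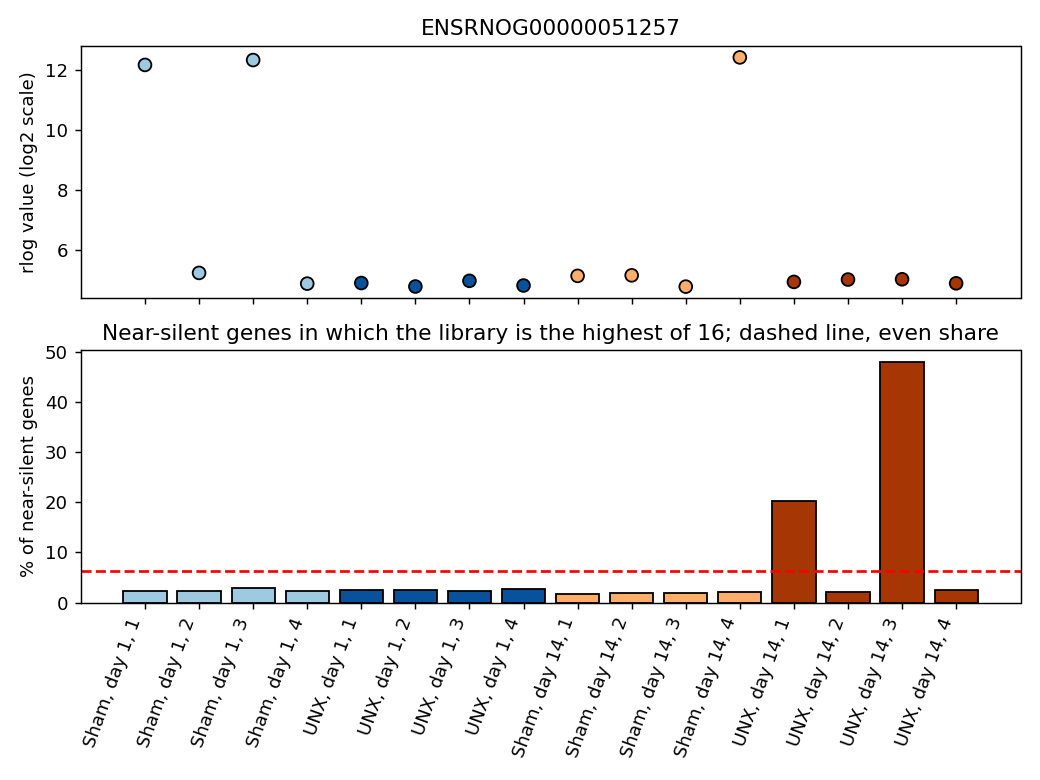
Upper panel, rlog value (log2 scale) of ENSRNOG00000051257 in each of the 16 libraries; lower panel, percent of the 5051 near-silent genes in which each library held the highest of the 16 values, with a dashed line at the even share of 6.25%. The gene was high in 3 sham libraries, and UNX day 14 libraries 3 and 1 were highest in 47.9% and 20.2% of near-silent genes.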

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

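Which groups held a sample far from the others was screened with Dixon's test in 40 groups of 4 libraries, and about 1 in 20 groups passes by chance; the tests of the near-silent genes were chosen after the signal was seen. For ENSRNOG00000000590, UNX day 14 library 4 stood at 10.551, below the other 3 UNX day 14 libraries at 10.8891 to 10.9301. For ENSRNOG00000006060, the highest sham day 1 value was 8.92586, above the other 3 at 8.80026 to 8.81877. For ENSRNOG00000051257, sham day 14 library 4 stood at 12.4167, above the other 3 at 4.76708 to 5.14425. On the first principal component, sham day 14 library 4 stood at 24.4814, above the other 3 sham day 14 libraries at 14.7751 to 16.1862. In all, 4 of the 40 groups passed.

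Signal outside the tested genes was found in 2 libraries. Among the 5051 near-silent genes, UNX day 14 library 3 held the highest of the 16 values in 47.8519% and UNX day 14 library 1 in 20.1544%. The 8 sham libraries, the controls, were highest in 1.70% to 2.99% each, and an even share would be 6.25%.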

How the results depend on the processing

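Fits without several libraries at once were chosen after the data were seen; the other alternatives were planned. The count of genes that differed between the sham groups stayed within 1.5 times of 6696 in 20 of 21 alternatives, and was 1234 when a difference of at least 0.5 was also required. Leaving out 1 library at a time moved it between 5951 and 6536. The counts for UNX were unstable. For day 1, 1 gene became 0 without the filter, with a mean value of at least 5, with median centring, with the robust variance model and with a difference of at least 0.5, and 2 with array weights and with a fit of the compared groups alone. The stricter filter removed the gene itself, whose mean is 4.69; otherwise the cause was not tested. For day 14, 8 genes became 0 without the filter, which raised the number tested to 22715, 3 without the variance trend, 2 with array weights, 0 with a fit of the compared groups alone, 58 at adjusted p under 0.10 and 1 with a difference of at least 0.5. The average over both ages gave 0 genes without the filter, without the trend, with array weights and with a difference of at least 0.5, and 2 with the robust model and at adjusted p under 0.10. The difference between ages gave 1 gene at adjusted p under 0.10.

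Leaving out 1 library at a time gave 0 to 2 genes for day 1, 0 to 90 for day 14, 0 to 10 for the average and 0 to 5 for the difference between ages. Without UNX day 14 libraries 1 and 3, day 14 gave 1 gene and the average 0. Without the 2 sham libraries apart on the second component, day 1 gave 9 genes, day 14 gave 3 and the difference between ages 4. Without the 3 sham libraries high in ENSRNOG00000051257, day 1 gave 9 genes, day 14 gave 2, the average 3 and the difference between ages 3, and the slope along the age difference for day 1 became 0.064. The causes were not tested. The 4 named genes that passed a test kept their direction in all alternatives run for them. Their UNX and sham values did not overlap, so leaving out libraries could not have reversed it. The slopes and the correlation of effects, none past its test, did change sign: leaving out 1 library moved the day 1 slope between −0.0018 and 0.037, the day 14 slope between −0.048 and 0.033 and the correlation between −0.043 and 0.12, and without the 2 sham libraries apart on the second component the day 14 slope was 0.033 and the correlation −0.044. Without the 3 sham libraries high in ENSRNOG00000051257 these were 0.033 and −0.033. Neither scaling moved the median difference of any contrast by over 0.01.

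Library numbers did not pair the libraries. Of 24 same-numbered pairs, 2 had a correlation of deviations over 0.1, the range was −0.228 to 0.119, and 2 of 16 libraries correlated best with their own number. With the number as a replicate block, day 1 gave 0 genes, day 14 gave 8 (7 higher, and 5 of them shared with the fit without the block), the average 2, the difference between ages 0 and age 6496. The alternatives planned for the gene lists were not run, since no list could be matched to the identifiers. Absolute depth is unknown, and changes of 0.25 on the log2 scale were recovered in 33% of simulated genes for day 1 and 39.5% for day 14, so small changes would often be missed.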

Other observations

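The splits of the samples, the test of highly expressed genes and the test of the spread of the sham libraries over both ages were fixed before their results were seen; the tests of the all-or-none gene, the tests of the origin of the near-silent signal and the tests of that spread at each age were chosen after the results were seen. Chance was argued against for the change with age. Of 35 splits of the 8 sham libraries, 1, the real one, gave as many as 6696 genes, and the highest other split gave 16. This is the smallest share 35 splits allow, and it was not adjusted for the other comparisons split. Chance could not be excluded for the UNX counts at each age or their average. For day 1, 3 of 35 splits gave at least 1 gene and the highest other gave 3. At an unadjusted p under 0.05, 3 of 35 splits gave as many as 1061 genes, the highest other giving 1181. For day 14, 2 of 35 splits gave at least 8 genes. The other split exchanged UNX library 4 with sham library 4 and gave 68 genes, several times the real count, which points to a structure among these samples that was not tested. At an unadjusted p under 0.05, 1 of 35 splits, the real one, gave as many as 2132 genes, the highest other giving 1986. That is the smallest share 35 splits allow. It lies under 0.05 for day 14 taken alone but comes to 0.057 over both ages, so chance was not excluded over both. The count at an unadjusted p under 0.05 fell to 1003 genes without UNX libraries 1 and 3, the lowest of the 6 pairs of UNX libraries left out. It was 1188 without libraries 1 and 2, 1086 without 2 and 3, and 1847 to 2205 without library 4 and any other. These fits were chosen after the data were seen. For the average over both ages 5 of 100 drawn splits gave at least 1 gene, the highest other giving 1. The splits decide nothing for the difference between ages, because a real count of 0 is met by all 100 of 100 drawn splits whatever the data, the highest other giving 1.

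ENSRNOG00000051257 was high in 3 sham libraries and low in the other 13. The sham operation alone as its cause was argued against, since 3 of the 8 sham libraries were high, a count already known when that test was written. RNA from another tissue was also argued against, since 0 other tested genes were higher by over 1 in the same 3 libraries and the next largest gap was 0.25. Pups of the other sex among the sham animals, which the labels give as male, may be an explanation, and cannot be told apart from others here. That would need Y-chromosome genes low in these 3 libraries, and 0 tested genes were low there and high in the other 13 by over 1, but without gene names it is not known whether such genes were measured. An inherited variant that some pups carried was not tested.

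In near-silent genes, UNX day 14 libraries 3 and 1 held the highest value far more often than the other 14 libraries. Higher depth as the cause was argued against, since library 1 was placed at 11 and library 3 at 8 of 16 in depth, and the libraries placed deeper than library 3 were highest in at most 2.79% of these genes. RNA from another tissue was argued against for library 3, which exceeded all other libraries by over 0.5 in 1 of 22715 genes, although the transform shrinks such gaps; for library 1, with 8 genes, it cannot be told apart from other causes, and both the scope of this count and its division by library were set after the values were seen. A small addition spread over all genes, such as genomic DNA or unspliced RNA, may account for the signal, since the share of genes in which library 3 was highest came down to 4.73% at mean values of at least 5, but it did not fall between the lowest classes, 47.8% and 48.0%, and library 1 stood at 10.4% at mean values of at least 5, up from 8.48% in the class below, so the test left this open for both. Background in near-silent genes alone was argued against as the source of the excess of small p-values after surgery on day 14. Among the 3494 genes with a mean value of at least 10, 22.9% had an unadjusted p under 0.05, against 7.78% after surgery on day 1. The day 14 share was 8.21% without libraries 1 and 3, the lowest of the 6 pairs left out. It was 11.1% without 1 and 2, 11.2% without 2 and 3, and from 19.4% (1 and 4) to 24.2% (2 and 4) in the 3 pairs with library 4. Library 2 was highest in 2.00% of near-silent genes, so these fits do not tie the fall to the signal of libraries 1 and 3. Another property of libraries 1 and 3 was not singled out either, and the cause was not tested.

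The sham libraries varied more than the UNX libraries, with a median variance ratio over genes of 1.75 after surgery on day 1 and 1.31 after surgery on day 14. Chance could not be excluded in the test first written, which covered both ages and whose larger exact permutation p was 0.286 (day 14). For day 1 taken alone the exact permutation p was 0.0286 (2 of 70 relabellings, the smallest an exact permutation allows). It comes to 0.057 over both ages, so chance was not excluded over both there either. The test of lower depth for day 1 gave a ratio of 2.39 among genes with a mean value of at least 10. It took counting noise to be small there, but absolute depth is unknown and the transform shrinks the spread of weakly expressed genes. The mean place in the depth order was 12.75 for sham day 1 and 5.5 for UNX day 1 (two-sided exact permutation test, p = 0.057, n = 4 each). Lower depth was therefore not excluded for day 1. For day 14 the mean place in the depth order was 6.75 for sham and 9 for UNX (two-sided exact permutation test, p = 0.6, n = 4 each). These places show no lower depth of the sham libraries, but with such a spread they cannot exclude it. A single library may account for day 14, where the ratio was 0.98 without sham library 4, and stayed open for day 1, where it was 1.34 without sham library 3. A biological difference between sham animals was not tested.

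Sham day 14 library 3 exceeded all other libraries by over 0.5 in 28 genes and sham day 1 library 3 in 19, of 22715. The deviations of sham day 1 library 3 and sham day 14 library 4 from their group means had a correlation across genes of 0.339. Both were picked because they lay apart in the same direction on the second component, so a positive correlation follows in part from that choice.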
